A study of Vulpes vulpes with 8 samples.

How the data were processed

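Gingival tissue of red foxes (Vulpes vulpes) diagnosed with or without hereditary hyperplastic gingivitis (HHG), a heritable overgrowth of the gum, was profiled on Affymetrix Canine 2 arrays. The array carries dog probe sets, so fox RNA was read through sequences of a related species. Per the labels' protocols, pieces of gingiva were put in an RNA stabilising solution, RNA was extracted with a kit for fibrous tissue with an added DNase step, and biotin-labelled RNA was made with a 3' in vitro transcription kit. Per the labels' protocols, some pieces came from animals euthanised in the pelting season and others from live anaesthetised animals in late spring. The labels do not assign a season to each fox, so the season could not be tested. The labels give a fox number, the disease status and the sex of each of the 8 animals: 5 affected (3 males, 2 females) and 3 unaffected (2 males, 1 female). Each array is 1 fox.

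The deposited table holds 1 linear intensity per probe set and array, the signal of MAS5 per the submitters' processing notes, which give no version. Background method, scaling target and detection calls are not given in the sources used here. The mean intensity with 2% of the probe sets trimmed at each end was 150.0 on every array of the deposited table, which is the scale the authors left the values on. The table had 43035 probe sets, of which 111 were controls. Of the other 42924, the annotation table used here gave 1 gene symbol for 29254 and several for 439, and 13231 were unnamed here. No gene was named from a probe set with several symbols.

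Intensities were taken as log2(signal + 16) with no further normalization. Controls were left out, and so was the 40% of probe sets with the lowest mean over the 8 arrays, which left 25754 probe sets. The offset shrinks the differences of dim probe sets, so each fold is on the log2(signal + 16) scale. Median signal ran from 28.6 to 33.7 over the arrays. Background was read per array as the 95th percentile of 42 probe sets for bacterial transcripts, and 63.4% to 74.7% of probe sets lay above it. The number of arrays limits the precision: the median standard error of a difference between the groups was 0.23 on the log2 scale.

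Groups were compared per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment, threshold 0.05), with group as the only term. Sex was tested with a term for group, and the difference of the disease effect between sexes as an interaction. Probe sets with an unadjusted p under 0.01 and a fold of at least 2 were counted as a description. For gene values, the probe set with the highest mean stood for each of 10824 genes. The 49 gene lists, of pathways and of cell type markers, held 1023 symbols, of which 811 were in the annotation and 673 were tested. Lists with at least 5 tested genes, 46 in all, were tested with limma's camera at a preset correlation of 0.01, then with the correlation estimated for each list, and with fry, which asks whether a list's genes move on balance one way without comparing them with other genes. A list score is the mean of the members' log2 values, each centred over the 8 foxes. Scores were compared with two-sided exact permutation tests over the 56 splits of 8 foxes into 5 and 3, where the smallest possible p is 0.0179.

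Genes were named by a rule: in each direction the 12 genes with the smallest p among those with a fold of at least 2, genes past the threshold first. Symbols that start with LOC or ENSCAFG and segments of immunoglobulins or T cell receptors were passed over there. From a list up to 2 members per direction could be named, and from the sex comparison 3 per direction. Of the lists tested, 12 are described with some of the members that the rule names, a choice made after values were seen. The lists of MHC class II genes and of the cell cycle were left out of those 12 after their values were seen and are given by count, median and test only, and FCER1G in the macrophage list was left out likewise. The comparisons, lists, naming rule and most alternatives were fixed before the data were examined. Alternatives covered the offset, normalization between arrays, the filter, sex as a covariate, each sex alone, array weights, the prior variance, 1 probe set per gene, a threshold of 0.1, other list tests and each fox left out in turn. Covariates for an actin ratio and for a tissue score, a fit without 2 foxes, scores centred within sets of foxes and the estimated correlation in each fit without 1 fox were added after seeing the data.

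The fits were tested on simulated arrays with the real means and spreads for affected against unaffected over 25754 probe sets, with 200 changed in each of 5 draws. Of probe sets changed by 1 on the log2 scale 20.4% were recovered, by 2 84.2% and by 3 96%. For lists, over 10824 genes, a shift of 0.5 was called in 20 of 20 draws. A factor shared by the members of a list with no change between groups was called in 10 of 20 draws with the preset correlation and in 0 of 20 with the estimated one. Apart from that factor the simulated probe sets varied independently, unlike those of the real arrays, so the rates of recovery may be too high. The factor also varied more over foxes than scores such as that of oxidative phosphorylation (SD 0.074), so its calls need not carry over to such lists. Plots were drawn with matplotlib 3.10.9.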

Results

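Expression was measured in the gingiva of 8 red foxes, 5 affected by HHG and 3 unaffected, with 1 array per fox. Foxes are named by their number in the labels: affected 19, 55 and 107 (males) and 381 and 757 (females), and unaffected 86 and 97 (males) and 402 (female). The arrays resembled each other closely, with a mean Pearson correlation across probe sets of 0.962 within the affected group, 0.957 within the unaffected group and 0.962 between the groups. Probe sets are not independent replicates, and these correlations describe the arrays only. No pair of arrays held identical columns of values.

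The first comparison asked which genes differ between affected and unaffected gingiva. LCN2, an iron-scavenging lipocalin of neutrophils and epithelium, read 309 ± 154 in affected (SD, n = 5) and 100.02 ± 36.1 in unaffected foxes (SD, n = 3). MMP9, a gelatinase, read 89.3 ± 52.4 against 26.6 ± 9.95, LTF (lactoferrin) 82.2 ± 54.4 against 21.1 ± 16.6, and PGLYRP1, which binds bacterial peptidoglycan, 106.0 ± 83.1 against 22.4 ± 17.9. CD68, a lysosomal protein of macrophages, read 344 ± 38.0 against 179 ± 109, and its second probe set differed by 0.31 where this one differed by 1.07 on the log2 scale, or by 0.55 without unaffected fox 97. None of these genes passed the threshold in limma (adjusted p = 0.9998 for each).

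The largest difference among the named genes was that of CELA1, a serine elastase, at 160 ± 96.6 (SD, n = 5) against 14.4 ± 10.8 (SD, n = 3), a log2 difference of 2.40 ± 0.47 (SE) with 1 of the 3 unaffected foxes at background. ABTB1 differed by 1.23 ± 0.26 (SE), NCCRP1, at background in 1 unaffected fox, by 1.04 ± 0.28, USP20, a deubiquitinating enzyme, by 1.01 ± 0.27, and COL27A1, a fibrillar collagen, by 1.74 ± 0.64, while the other probe sets of COL27A1 ranged from -0.068 to 1.18 and those of USP20 from 0.38 to 0.81. FOS, an immediate-early transcription factor, differed by 1.53 ± 0.58, and ADA, adenosine deaminase, by 1.06 ± 0.43. For CELA1, ABTB1, LCN2, NCCRP1, MMP9, USP20 and CD68 each affected fox read above each unaffected fox. Such complete separation was seen in 625 probe sets, 2.43% of those tested, where chance gives 3.57%.

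Among genes with lower means in affected foxes, only 10 of those the rule allows to be named had a fold of at least 2. GJA1, a gap junction protein, read 302 ± 189 (SD, n = 5) against 694 ± 170 (SD, n = 3), and its second probe set differed by -1.59 on the log2 scale. ANXA4, an annexin, read 346 ± 197 against 652 ± 136, CYP24A1, which inactivates vitamin D, 202 ± 149 against 364 ± 118, and SLC39A6, a zinc transporter, 101 ± 32.5 against 250.1 ± 146. CAMSAP3, which binds microtubule ends, differed by -1.06 ± 0.27 (SE), GPX7 by -1.16 ± 0.30, PBRM1, a chromatin remodelling subunit, by -1.07 ± 0.28 and AGK, a mitochondrial lipid kinase, by -1.36 ± 0.40. PTS, an enzyme of tetrahydrobiopterin synthesis, differed by -1.15 ± 0.53, and POF1B by -1.21 ± 0.87. The GPX7 and AGK probe sets were at background in 2 and 3 of the 5 affected foxes. POF1B was at background in 1. The second probe set of PTS differed by -0.35, and the other probe sets of PBRM1 by -0.39 and -0.25. Within foxes of low 5' actin, described further on, the PTS difference was 0.14, as that of CYP24A1 was 0.087 within foxes of high 5' actin. The adjusted p of each was 0.9998. POF1B differed by -2.22, -0.72 and -0.68 without unaffected foxes 86, 97 and 402 and by -0.76 without affected fox 55, PTS by -0.57 and -1.87 without unaffected foxes 86 and 402, and SLC39A6 by -0.67 without unaffected fox 97.

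**Figure D1:**
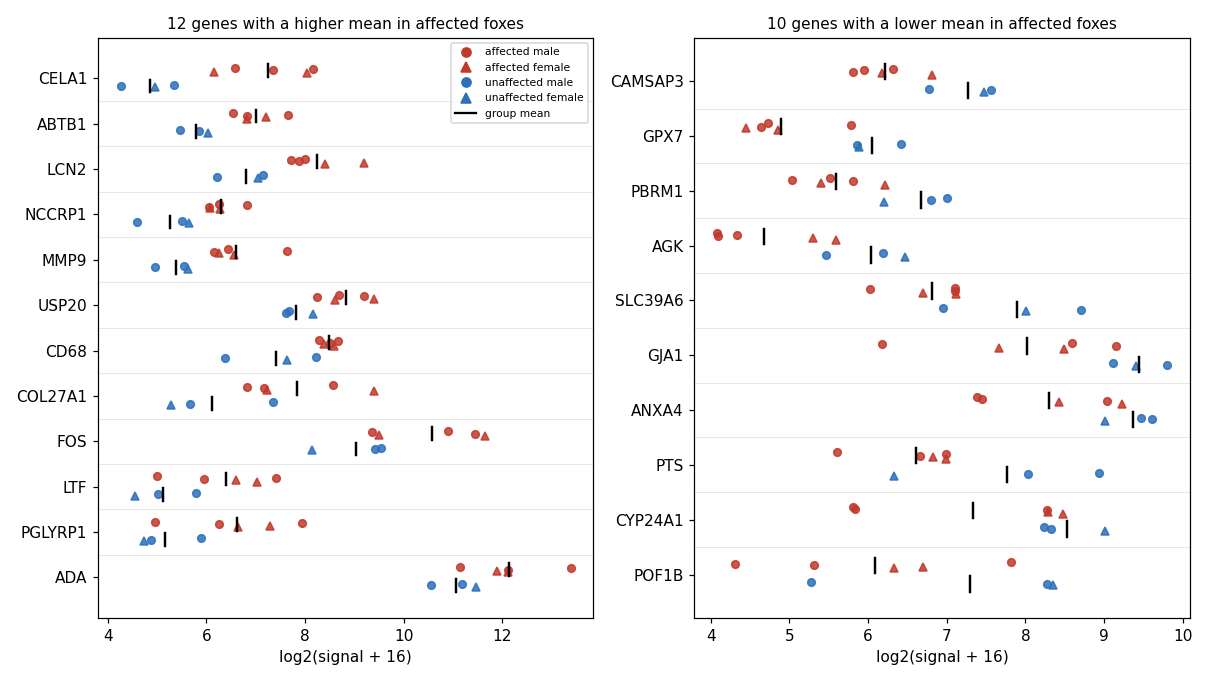
Each point is 1 fox, on a log2(signal + 16) axis, with affected foxes in red, unaffected in blue, males as circles, females as triangles and group means as black bars. The left panel holds the 12 named genes with higher and the right panel the 10 named genes with lower means in affected foxes. The groups of LCN2 do not overlap, while those of GJA1 do, and none of the 22 genes passed the threshold.

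Across all 25754 probe sets, limma called 0 higher and 0 lower at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 693, where 1288 would be expected by chance. With an unadjusted p under 0.01 and a fold of at least 2 there were 16 higher and 10 lower. Of the 10824 genes 0 passed. Without unaffected fox 86 the unadjusted counts were 82 higher and 44 lower, and without affected fox 19 they were 39 higher and 8 lower. They were 31 and 16 without unaffected fox 402, 18 and 16 without affected fox 107, 18 and 19 without affected fox 757, and 12 and 5 without affected fox 55.

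The probe set with the smallest p was 1 of 4 for REEP5, a protein that shapes the endoplasmic reticulum; it was singled out after its values were seen. It read 522 ± 87.0 in affected foxes (SD, n = 5) and 1350 ± 173 in unaffected foxes (SD, n = 3), a log2 difference of -1.35 ± 0.17 (SE) at an adjusted p of 0.791 in limma. The 3 other REEP5 probe sets differed by -0.33, -0.20 and -0.13, and in the second of these the groups did not overlap either, with 495.3 to 634.7 in affected and 644.9 to 684.3 in unaffected foxes.

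Gene lists were compared next, to ask whether genes of a pathway or cell type moved together. In the hypoxia and glycolysis list 19 of 22 members had higher means in affected foxes, with a median log2 difference of 0.24. GPI and PGK1, both glycolytic enzymes, read 5132 ± 995 against 3628 ± 545 and 3224 ± 434 against 2471 ± 387 (SD, n = 5 and n = 3), while PFKFB3, a regulator of glycolysis, differed by -0.53. PGK1 differed by 0.38 on the log2 scale, or 0.25 without unaffected fox 86, and PFKFB3 by -0.34 and -0.16 without affected fox 55 and unaffected fox 97. The list was called higher by camera (adjusted p = 0.000149), and the call was lost at an adjusted p = 0.809 with an estimated correlation. In oxidative phosphorylation 23 of 28 members had higher means by small amounts (median 0.070), among them SDHB and ATP5F1B, which differed by 0.22 and 0.23, the latter by 0.14 without unaffected fox 86. The camera adjusted p was 0.0223, and the adjusted p = 0.900 with an estimated correlation. Without affected fox 55, unaffected fox 97 or affected fox 107 that list gave 0.0694, 0.167 and 0.0906. Its median was 0.11 without affected fox 19 and without unaffected foxes 86 and 402, 0.046 without affected fox 55 and 0.045 without unaffected fox 97.

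Defence genes formed the next group. In antimicrobial peptides and mucosal defence 15 of 17 members had higher means in affected foxes (median 0.31, camera adjusted p = 0.00186; adjusted p = 0.900 with an estimated correlation). The members were led by LCN2 and LTF, while LPO and CAMP, a lactoperoxidase and a cathelicidin, differed by -0.53 and -0.41. The second LPO probe set differed by 0.075, and the first was at background in 2 affected foxes and differed by -0.35 without affected fox 19. CAMP differed by -0.17 without unaffected fox 86. The camera adjusted p was 0.0565 without unaffected fox 402, and the median was 0.57, 0.16 and 0.53 without affected fox 19, affected fox 55 and unaffected fox 86.

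In the neutrophil list 7 of 10 members had higher means (median 0.079, mean 0.38, camera adjusted p = 0.0238; adjusted p = 0.809 with an estimated correlation). CAMP and CD177, a neutrophil surface protein at background in 2 affected foxes, differed by -0.41 (-0.17 without unaffected fox 86) and -0.28. Camera gave an adjusted p of 0.127, 0.0551, 0.206 and 0.0707 without unaffected fox 97, affected fox 107, unaffected fox 402 and affected fox 757. The median was 0.17, 0.21 and 0.14 without affected foxes 19, 55 and 381, and 0.56, 0.14 and 0.039 without unaffected foxes 86, 97 and 402.

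In the macrophage and monocyte list 16 of 18 members had higher means (median 0.19, camera adjusted p = 0.00143; adjusted p = 0.934 with an estimated correlation). They included CD68 and LGMN, a lysosomal protease, at 563.1 ± 69.95 against 391 ± 119 (SD, n = 5 and n = 3), although the other LGMN probe sets differed by 0.20 to 0.52. The score difference of this list was -0.020 within males and 0.93 within females, where 1 fox was unaffected. Camera gave an adjusted p of 0.251, 0.0551 and 0.166 without unaffected fox 97, affected fox 107 and unaffected fox 402. The median was -0.0055, 0.70 and 0.078 without unaffected foxes 97, 86 and 402, and 0.51 without affected fox 19.

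Type I interferon response genes ran the other way, with 22 of 27 members lower in affected foxes (median -0.22, camera adjusted p = 0.0102; adjusted p = 0.934 with an estimated correlation). USP18 and MX2, both induced by interferon, read 84.98 ± 26.2 against 138 ± 39.5 and 212 ± 73.3 against 378 ± 218 (SD, n = 5 and n = 3). The MX2 difference was -0.71 on the log2 scale, and -0.29 without unaffected fox 86, which read 628 against 230 and 275 in the other unaffected foxes. Without unaffected fox 86 the list median was 0.066 and the camera adjusted p 0.534, without affected fox 381 the adjusted p was 0.136, and without unaffected fox 402 the median was -0.44. The score difference was -0.39 within males and 0.043 within females, where 1 fox was unaffected.

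Cornified envelope genes, which build the outer layer of keratinised epithelium, had higher means in 14 of 20 members (median 0.47, camera adjusted p = 0.0346; adjusted p = 0.934 with an estimated correlation). The proteases KLK7 and KLK5, which act in shedding of that layer, differed by 0.95 and 0.87 and were at background in 2 and 1 of the affected foxes and in as many unaffected ones. Among the lower members TGM5 and DSC1 differed by -0.42 and -0.38, with DSC1 at background in 2 affected foxes and 1 unaffected fox. Without affected fox 19, which read 148 against 2.29 to 52.9 in the other affected foxes, KLK7 differed by 0.50. The score difference was 1.17 within males and -0.91 within females, and without unaffected fox 86 the median was -0.53 (camera adjusted p = 0.0207; adjusted p = 0.813 with an estimated correlation). Without affected foxes 19, 107 and 381 the camera adjusted p was 0.523, 0.0551 and 0.136. The median was 0.14 and 0.31 without affected foxes 19 and 381, and 0.78 and 0.89 without unaffected foxes 97 and 402.

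The lists given next also bear on tissue overgrowth or on inflammation. With all foxes included, camera did not call them, unlike the macrophage, neutrophil and antimicrobial lists above. In collagen and extracellular matrix 17 of 23 members had higher means (median 0.099, camera adjusted p = 0.175), with COL12A1 at 0.42 and POSTN at -0.41. The list median was -0.17 without unaffected fox 402, and the score difference was -0.22 within males and 0.78 within females. COL12A1 was 0.71, 0.26 and 0.24 without unaffected fox 86, unaffected fox 97 and affected fox 757, and POSTN -0.21, -0.15 and -0.75 without affected fox 55, unaffected fox 86 and unaffected fox 97. Inflammatory cytokines and chemokines had 22 of 31 higher (median 0.18, adjusted p = 0.186), with IL1B and CXCL8 differing by 0.72 and 0.86 and CXCL10 and TNF by -0.92 and -0.46. IL1B was at background in 1 unaffected and TNF in 1 affected fox, and the second CXCL10 probe set differed by -0.41. CXCL8 differed by 0.45 without unaffected fox 97, CXCL10 by -0.48 without unaffected fox 86 and TNF by -0.30 without affected fox 381. In RAS-ERK signalling 7 of 16 members were higher (median -0.019, adjusted p = 0.801), with RASA1 and PHLDA1 at 0.47 and 0.67 and MAP2K1 at -0.34, while the other probe sets of RASA1 ranged from -0.053 to 0.33 and those of MAP2K1 from -0.38 to 0.12. RASA1 was 0.31 without unaffected fox 97, PHLDA1 0.43 without affected fox 55, and MAP2K1 -0.23 and -0.22 without affected fox 381 and unaffected fox 402. TGF-beta response had 7 of 20 higher (median -0.072, adjusted p = 0.801), and the T cell list 7 of 16 (median -0.049, adjusted p = 0.856). In the cell cycle list 18 of 33 members were higher (median 0.0060, adjusted p = 0.569), and in MHC class II presentation 1 of 13 (median -0.14, adjusted p = 0.538). Without unaffected fox 86 camera called collagen and extracellular matrix (adjusted p = 1.22e-05), inflammatory cytokines and chemokines (5.57e-05) and the T cell list (8.12e-05) higher, at an adjusted p = 0.736, 0.736 and 0.754 with an estimated correlation. It also called collagen and extracellular matrix without affected fox 55 (adjusted p = 0.00233; adjusted p = 0.859 with an estimated correlation) and inflammatory cytokines and chemokines without affected fox 19 (adjusted p = 0.0114; adjusted p = 0.861 with an estimated correlation).

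**Figure D2:**
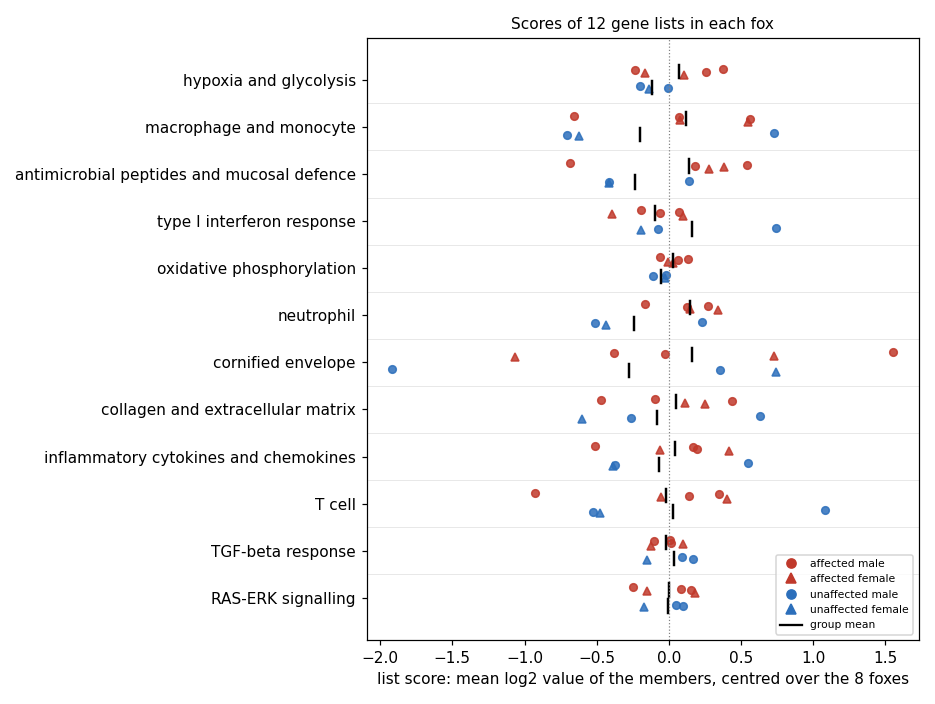
Each point is the score of 1 gene list in 1 fox: the mean log2 value of its members, each centred over the 8 foxes. Affected foxes are red and unaffected blue, males circles and females triangles, and black bars are group means; the foxes of both groups overlap in each of the 12 lists, and the cornified envelope scores spread widest, from -1.92 to 1.56.

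In all, camera with the preset correlation called 6 lists higher and 1 lower of 46 tested, while with an estimated correlation and with fry 0 lists passed. With an estimated correlation 0 passed in each fit without 1 fox too. That test also called 0 lists in each of the 56 splits of the foxes into 5 and 3. A call lost under it thus does not show that a list is unchanged. Camera called 15 higher without unaffected fox 86, 2 higher without affected fox 107, 3 lower without unaffected fox 97 and 0 lower without affected fox 381. By exact permutation of the list scores 0 of the 46 had an unadjusted p under 0.05 (smallest 0.0893). The median and mean of members differed in sign from each other or from the test in 6 lists, T cell and RAS-ERK signalling among them. Of list members 0 passed when adjusted over all genes. With 46 lists each adjusted alone and no correction across lists, some passes are expected by chance. When adjusted over the list alone, LCN2 passed in the antimicrobial and neutrophil lists, MMP9 in the neutrophil list, and FLT4, FZD7 and CMA1 in the lists of lymphatic endothelium, wnt and notch signalling and mast cells. The lists of lymphatic endothelium and mast cells held only 5 and 6 tested genes. In the matrix proteolysis list, which also holds MMP9, the smallest p adjusted over the list alone was 0.0774 in limma. FLT4, a receptor of lymphatic vessels, read 49.3 ± 8.75 against 19.6 ± 15.9, FZD7, a wnt receptor, 32.3 ± 5.72 against 11.6 ± 6.03, and CMA1, mast cell chymase, 33.9 ± 11.9 against 9.64 ± 5.04 (SD, n = 5 and n = 3). The second probe sets of FLT4 and FZD7 differed by -0.043 and -0.15. FLT4, FZD7 and CMA1 were at background in 2, 1 and 2 of the unaffected foxes, and CMA1 in 1 affected fox too.

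The array controls for beta-actin split the foxes into sets that each held affected and unaffected foxes. The 5' actin probe set read 7831 to 8868 in foxes 86, 97, 107 and 757 and 1354 to 2336 in foxes 19, 55, 381 and 402, while 1 of the 3' actin probe sets read 6266 to 8541 over all 8. The 3' probe set of the same control series, which the ratio uses, was itself higher in the first 4 foxes, at 12688 to 14956 against 7585 to 9722. The log2 ratio of 5' to 3' actin was -1.77 ± 1.02 (SD, n = 5) in affected and -1.08 ± 0.65 (SD, n = 3) in unaffected foxes (two-sided exact permutation p = 0.321). Within the foxes of high and of low 5' actin, the group difference was 1.46 and 1.26 for LCN2, 2.88 and 2.00 for CELA1, 0.29 and 0.13 for the hypoxia and glycolysis score, 0.54 and 0.45 for macrophage and monocyte, 0.37 and 0.50 for the antimicrobial list and 0.37 and 0.52 for neutrophil. It was -0.31 and 0.020 for type I interferon response, 0.24 and -0.11 for cornified envelope and 0.11 and 0.047 for oxidative phosphorylation, so the first 2 of these kept no single direction within both sets. Only 1 unaffected fox lay in the low set.

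The sex of the foxes was compared next, which also checks the labels. A probe set for EIF2S3, a translation initiation factor, read 747 to 970 in the 5 males and 1.36 to 2.63 in the 3 females, where it lay at background. It was at least 31.7-fold higher in males, with an adjusted p of 3.41e-06 in limma. Its readings matched the sex in the labels in 8 of 8 foxes. The 2 other EIF2S3 probe sets differed the other way, by -0.54 and -0.57 (male minus female, adjusted p = 0.9999 in limma). The male excess is thus that of 1 probe set and cannot be read as a male excess of EIF2S3. Which transcript that probe set reads was not tested. The first probe set was the only one past the threshold: limma called 1 higher and 0 lower in males, with 589 at an unadjusted p under 0.05, and 1 lower without affected fox 55. It was named after its values were seen.

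Other genes with the smallest p for sex did not pass (adjusted p = 0.9999 for each). ERBB4, a growth factor receptor, read 98.2 ± 26.9 in males (SD, n = 5) and 31.6 ± 14.6 in females (SD, n = 3), SDC4, a proteoglycan, 396 ± 160 against 148 ± 39.8, and PLSCR3 52.3 ± 8.36 against 21.5 ± 7.16. TSPAN8 read 59.1 ± 16.3 in males against 179 ± 58.3 in females, SOSTDC1, a secreted BMP antagonist, 155 ± 34.2 against 299 ± 44.6, and KDM6A, an X-linked histone demethylase, 113 ± 19.9 against 212 ± 16.4. The log2 differences of SDC4, TSPAN8 and KDM6A were 1.28, -1.37 and -0.84, and their other probe sets gave 0.26 to 0.32, -0.78 and -0.43. For the difference of the disease effect between males and females limma called 0 probe sets, with 639 at an unadjusted p under 0.05. The females include 1 unaffected fox, which limits that comparison.

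**Figure D3:**
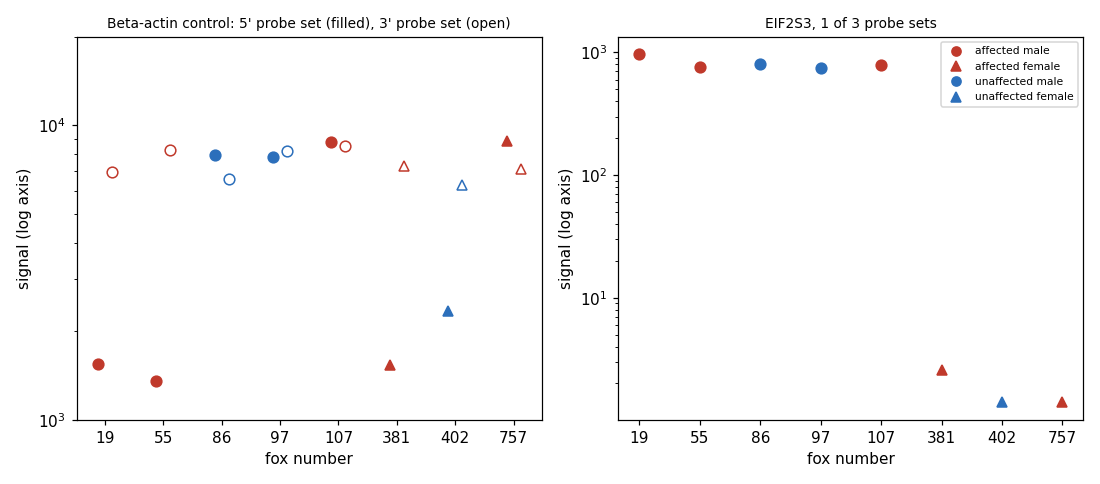
Signal on log axes for each of the 8 foxes, coloured by disease status (red affected, blue unaffected) with males as circles and females as triangles. On the left the 5' actin probe set (filled) falls into 4 foxes at 7831 to 8868 and 4 at 1354 to 2336 while the 3' probe set (open) stays between 6266 and 8541; on the right the EIF2S3 probe set reads 747 to 970 in males and 1.36 to 2.63 in females.

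Differences between foxes of 1 group were large beside those between groups. The first principal component of the log2 values held 37.4% of the variance. Along it, foxes with high cornified envelope scores had low T cell scores: over the 8 foxes Pearson's r was -0.945 (exact permutation p = 0.000769, adjusted p = 0.00923) and Spearman's rho -0.929 (exact permutation p = 0.00223, adjusted p = 0.0183), over a family of 12 relations chosen after the data were seen. Without unaffected fox 86 and affected fox 19, the foxes farthest from the median, r was -0.807. No correlation was computed inside a single disease group or actin set, each of which holds under 6 foxes. With the scores centred on the mean of each disease group, r over the 8 foxes was -0.958 and rho -0.976 (exact permutation within groups, p = 0.00278 and 0.00694), and centred on the mean of each actin set they were -0.951 and -0.952 (exact permutation within sets, p = 0.00347 for both).

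**Figure D4:**
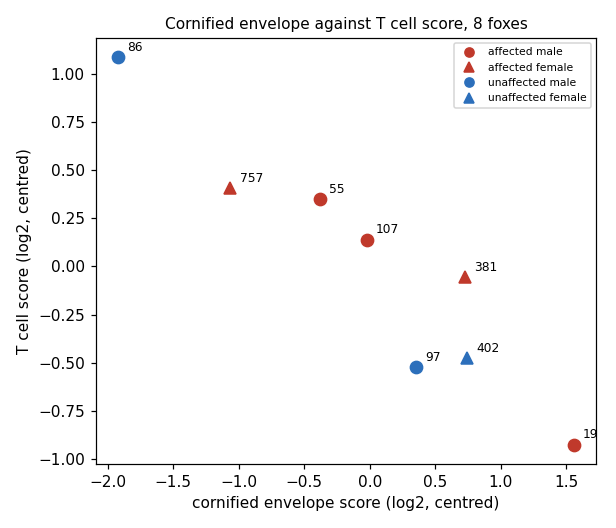
Each point is 1 fox, numbered as in the labels, with the cornified envelope score on the horizontal and the T cell score on the vertical axis (both log2, centred). Affected foxes are red and unaffected blue, males circles and females triangles; unaffected fox 86 and affected fox 19 lie at opposite ends, and the relation has an r of -0.945.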

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

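The tests of actin degradation, of the EIF2S3 probe set over other splits, of disease status, of epithelium and of other REEP5 probe sets were chosen only after the results were seen; those of second probe sets, of scaling and of other splits were written before.

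Of 68 group values tested, 4 had 1 fox far from the rest, where chance gives 3.4. MMP9 read 181.7 in affected fox 55 against 55.3 to 78.4 in the other affected foxes, a gap of 0.725 of the range of log2 values. GPI read 6903 in affected fox 55 against 4614 to 4865, a gap of 0.868 of the range. PTS read 32.8 in affected fox 19 against 85.5 to 110.8, a gap of 0.767. Among males, the EIF2S3 probe set read 970.3 in affected fox 19 against 747 to 800.3, a gap of 0.738. Exact permutation of the labels within sexes called no list score different in its disease effect between males and females (46 lists, 30 arrangements, where 0.0333 is the smallest possible p). With 1 unaffected female it could hardly call any, so it does not show equal effects. The effect in males minus that in females ran from -1.29 for complement to 2.08 for cornified envelope.

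Results were compared with those of other splits of the 8 foxes. For probe sets past the adjusted threshold the real value was 0, so all 56 of the 56 splits are as large by construction and this count tests nothing; the highest other split gave 170. For probe sets with an unadjusted p under 0.01 and a fold of 2 the real value was 26, and 37 of 56 splits gave as many, up to 666. For gene lists the real value was 7, and 30 of 56 splits gave as many, up to 21, so chance could not be excluded for the last 2 counts. For male against female the real value was 1, and 4 of 55 usable splits gave as many, up to 712, so the count alone does not exclude chance. For the EIF2S3 probe set behind it chance is argued against: its p of 1.02e-11 in limma, without a group term, was lower than the smallest p of each other of the 56 splits, the next being 3.92e-08. The splits that called 170 and 40 probe sets set foxes 19, 97 and 402, and foxes 86, 107 and 757, against the rest, which points to a structure of the samples. The first trio is 3 of the 4 foxes with the highest cornified envelope scores. The second is 3 of the 4 with the lowest cornified envelope and the highest T cell scores, and also 3 of the 4 of high 5' actin, so the tissue score bears on both splits; values within the actin sets stand in the report.

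The 5' actin signal split the foxes 4 and 4. RNA broken down from the 5' end in all transcripts would lower the GAPDH ratio too. That ratio differed by -0.11 ± 0.13 (SE) on the log2 scale between the same sets, against 1.64 for actin, and a second GAPDH pair by -0.29 ± 0.35. The first GAPDH ratio also followed sex, at 1.78 to 1.89 in males and 2.17 to 2.41 in females, and the sets were not balanced by sex. The GAPDH values argue against a loss as large in GAPDH as in actin and cannot speak for other transcripts. Within actin the gap grew toward the 5' end: a middle probe set read 2646 to 4102 in the low and 9088 to 10160 in the high foxes. Breakdown that spares GAPDH stays open. Disease status as the whole cause is argued against by affected foxes that span the range of all 8. The exact permutation p of 0.321, from 5 foxes against 3, cannot exclude a part for it. An effect on parts of transcripts stays open: second probe sets of the 200 genes most tied to the actin ratio kept a share of the slope that was 0.818 of the share kept for the tissue score, and 95% of values over resampled genes lay between 0.709 and 0.938, which spans the bound of 0.8 set in advance. A step of handling that the labels do not assign to foxes, such as the season of collection, may lie behind the split and was not tested.

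Cornified envelope scores were low where T cell scores were high across foxes. Less epithelium in the piece taken was tested with the basal keratinocyte score, which rose by 0.079 ± 0.072 (SE) per unit of cornified score, less than asked for. The members of that list hardly moved together, with an estimated correlation of 0.058 against 0.69 for cornified envelope. Its score may therefore be a poor gauge of epithelium, and less epithelium stays open. Scaling of the arrays is argued against by a correlation of -0.934 after quantile normalization. Disease status as the whole cause is argued against by affected foxes that alone span 72.0% of the range. With scores centred on the mean of each disease group, r was still -0.958. The exact permutation p of 0.732, from 5 foxes against 3, cannot exclude a part for disease status. What else sets this relation stays open and was not tested.

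The REEP5 probe set with the smallest p differed between the groups by -1.35 on the log2 scale, and a second REEP5 probe set also separated them, with 495.3 to 634.7 in affected and 644.9 to 684.3 in unaffected foxes. A change of the whole transcript by the size of the first is argued against: the other 3 probe sets differed by -0.22 ± 0.07 (SE) on average, less than the 0.5 asked for. A smaller change of the whole transcript stays open, as all 4 probe sets were lower in affected foxes, and some may read other transcript forms. Chance stays open, since 22 of 56 splits gave a smallest p as low.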

How the results depend on the processing

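The fits with the actin ratio or the tissue score (cornified minus T cell) as a covariate, the fit without foxes 19 and 86, scores centred within disease groups or actin sets, and the estimated correlation without 1 fox were chosen after seeing the data. No paired analysis was possible because the groups share no fox number. Counts past the adjusted threshold were 0 higher and 0 lower in each setting except without foxes 19 and 86, which gave 17 higher. Those foxes lie at opposite ends of the tissue score and in opposite groups, so leaving them out moves the group means of that score apart. Whether this lies behind the 17 calls was not tested. The other 14 such pairs gave 0. Of 1013 values of 47 of the named genes 1011 kept their direction and none passed, with a smallest adjusted p of 0.132 in limma. The genes were picked from fits to these same foxes, so kept direction was likely from the start and is no test of them. Leaving out 1 fox moved the difference of 19 of the 47 by over 1.5 times. With female foxes alone PTS was 0.57 and KLK7 -0.016. All 91 values of genes named for sex kept direction and side of the threshold. The interaction count was 0 in each setting, and the correlation of cornified and T cell scores ran from -0.971 to -0.807. Dim probe sets limit the rest, as the offset sets their differences.

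Unadjusted counts (16 higher, 10 lower) changed by over 1.5 times as follows: offset 1, 48 higher; offset 64, 3 and 2; quantile normalization, 6 lower. They were 5 and 1 with the lowest 70% left out (fewer probe sets), 7 and 4 with 1 probe set per gene (fewer tested), 36 and 30 in males alone, 35 and 16 in females alone and 29 higher with array weights. They were 25 and 5 with the actin covariate, 41 higher with the tissue score, and 336 and 110 without foxes 19 and 86. Leaving out 1 fox gave 12 to 82 higher and 5 to 44 lower. Lists (6 higher, 1 lower) became 3 higher with quantile normalization, 2 lower in males alone, 13 and 0 with array weights, 0 and 0 with the estimated correlation, 0 and 0 with fry, 13 and 0 with the actin covariate, 11 and 0 with the tissue score and 19 higher without foxes 19 and 86. Leaving out 1 fox gave 2 to 15 higher and 0 to 3 lower, and 0 and 0 each time with the estimated correlation. For sex, leaving out 1 fox gave 1 to 1 higher and 0 to 1 lower. For the settings without a stated reason, and for the fit without foxes 19 and 86, the cause was not tested.

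The direction of the test turned for these lists (median log2 difference). In males alone collagen gave -0.22, inflammatory cytokines -0.080, T cell -0.46 and RAS-ERK -0.13. In females alone type I interferon gave 0.10, cornified envelope -0.85 and TGF-beta 0.050. Without foxes 19 and 86 type I interferon gave 0.042 and cornified envelope -0.77. The T cell test turned with offset 64 (-0.032) and with fry (-0.049), and the RAS-ERK test with no filter (-0.042). Leaving out 1 fox gave T cell -0.28 to 0.47, RAS-ERK -0.16 to 0.050, type I interferon -0.44 to 0.066, cornified envelope -0.53 to 0.89, collagen -0.17 to 0.54, inflammatory cytokines -0.013 to 0.47 and TGF-beta -0.20 to -0.031. With the estimated correlation as well, tests turned with the same medians, among them T cell without 107 (-0.096) and 402 (-0.26), RAS-ERK without 107 (-0.089) and 757 (-0.062) and TGF-beta without 757 (-0.077). Cases where the median alone turned, with the test still higher, include macrophage in males alone (-0.019) and without fox 97 (-0.0055), oxidative phosphorylation in females alone (-1.75e-05) and cornified envelope with array weights (-0.037). They also include inflammatory cytokines without fox 402 (-0.0065) and RAS-ERK without fox 97 (0.050). Medians of T cell ran from -0.46 to 0.73 and of RAS-ERK from -0.16 to 0.22 over all alternatives. Of 394 list values 232 kept direction and side, 104 lost the call (hypoxia and glycolysis without foxes 19 and 86 among them), 18 gained one and 40 turned. The lost calls include those with the estimated correlation, which called 0 lists in each of the 56 splits and so could hardly keep one. Over all alternatives the largest adjusted p was 0.990 for each called list, from the estimated correlation without affected fox 757. The smallest were 2.82e-07 (hypoxia), 1.22e-16 (macrophage), 8.41e-07 (antimicrobial), 1.75e-05 (interferon), 0.00372 (oxidative phosphorylation), 0.000441 (neutrophil) and 1.36e-06 (cornified envelope). With the preset correlation camera called hypoxia and glycolysis in each fit without 1 fox (adjusted p 2.82e-07 to 0.0144). Each other called list lost its call in at least 1 of those fits.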

Other observations

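These tests were chosen after the data were seen. Over 12 relations across the 8 foxes, scores of immune lists and of endothelium were lower where the cornified envelope score was higher. Plasma cell genes had an r of -0.849 (exact permutation p = 0.00687, adjusted p = 0.0165) and a rho of -0.905, complement genes -0.852 and -0.905, B cell genes -0.875 and -0.857, and MHC class II genes -0.835 and -0.786 (adjusted p = 0.0559 for that rho, by exact permutation). Endothelium genes had an r of -0.836 and a rho of -0.762 (adjusted p = 0.0166 and 0.0630, by exact permutation), cytotoxic and NK cell genes -0.838 and -0.857, and macrophage and monocyte genes -0.804 and -0.714 (adjusted p = 0.0230 and 0.0768, by exact permutation). Activated keratinocyte genes went with the cornified envelope score, with an r of 0.884 (adjusted p = 0.0165) and a rho of 0.738 (adjusted p = 0.0688), both by exact permutation. Collagen and extracellular matrix genes had an r of -0.568 and basal keratinocyte genes one of 0.408, with adjusted p of 0.156 and 0.315 by exact permutation. Without foxes 86 and 19 r was -0.704 for plasma cell, -0.621 for complement, -0.598 for B cell, -0.409 for MHC class II, -0.581 for endothelium, -0.686 for cytotoxic and NK cell, -0.663 for macrophage and monocyte and 0.943 for activated keratinocyte genes.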
